A study of Homo sapiens with 2 samples.

How the data were processed

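Poly(A) RNA was profiled from Caco-2 cells, a human colorectal adenocarcinoma line that forms enterocyte-like layers, in 2 sequencing libraries. The first was made from total RNA (the mRNA library). The second was made from RNA recovered with ribosome-nascent chain complexes (the RNC-mRNA library), which is meant to hold mRNAs being translated. Per the labels' protocols, poly(A) RNA of both kinds was fragmented by heat, copied into cDNA and amplified by PCR. Molecular identifiers and a strand-preserving step are not named in the labels.

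The values are RPKM, reads scaled by transcript length in kilobases and by the library's total, for each gene, per the file headers, and were computed by the authors before deposition. The table pairs each of 23709 gene symbols with 1 RefSeq record, of which 18646 are protein-coding (NM) and 5063 are non-coding (NR) records. The label belongs to the record and not to the gene: some protein-coding genes, such as KRT8, CARS and SARS, are paired with an NR record. No symbol occurs more than once. The genome build is hg19, per the submitters' processing notes. The mapping and counting software is not given in the sources used here, nor is the handling of reads that fit several genes. No coordinates are reported, because the table holds none and the annotation used here (GENCODE release 29) is on another build.

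The depth of each library was worked out from the RPKM values. An RPKM is a whole number of reads scaled by transcript length and by the library's total. The total was taken as the whole number at which most genes of known transcript length held a whole number of reads, within the rounding of 7 printed digits. This gave 9640364 reads for the mRNA library, where 2591 genes came out whole against 1750 at the next best total. It gave 11083302 reads for the RNC-mRNA library, where 2345 genes came out whole against 1655. For each gene, the fewest whole reads that explain both RPKM values were then found, allowing a relative error of 2e-07 beyond rounding. These fewest reads cannot exceed the true reads if the totals are right, and they sum to 86.8% and 86.9% of the totals. The median expressed gene rests on at least 258 reads in the mRNA library and 280 in the RNC-mRNA library. They were used for exact Clopper-Pearson 95% intervals of single-gene ratios, for the limit that a count of 0 allows (3 reads) and for an alternative filter on reads. PCR copies are not independent molecules, so these intervals and limits cover counting error only.

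The translation ratio of a gene is its RNC-mRNA RPKM over its mRNA RPKM. It was computed as log2((RNC-mRNA + 0.1) / (mRNA + 0.1)), which understates the ratio of weakly expressed genes. Expressed genes are the 13402 with a mean RPKM of at least 1 over both libraries. RPKM values are relative to each library's total, so the centre of the ratios is set by normalization. Ratios are therefore given relative to the median of all expressed genes, on the log2 scale unless called a fold. Each group has 1 library, so there is no replicate check, and no p-value, SD or standard error is given. A difference of at least 2-fold from the median was used as a rule of size in place of a test.

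The groups of genes compared are 37 gene lists. For each, the median relative ratio of its expressed members is given with the order-statistic 95% interval of a median, which describes the spread over members and not over cultures. The median was placed by percentile among 10000 random lists of the same size, drawn from other genes in 20 bins of mean log2 RPKM. A list with at least 5 expressed members was described as standing apart at a percentile of at most 2.5 or at least 97.5. Of 2229 list entries, 2212 were matched in the table, older symbols included. SNHG17, ZFAS1, CCAT1, SELENOF and the 13 mitochondrially encoded mRNAs were not matched and are not analysed here. The ratio was also set against mean log2 RPKM, and against transcript length, taken as the length nearest a reference transcript at which both values are whole reads (98.3% of expressed genes).

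The genes named were chosen by rule: the 10 of highest RPKM in each library, and the 10 highest and 10 lowest ratios among genes with a mean RPKM of at least 10. For each list, the rule adds the 2 members of highest mean RPKM and the members of highest and lowest ratio. For lists standing apart, it adds up to 4 more members in the list's direction. Some genes this rule selects are not reported here. The lists, the rule for named genes and the following alternatives were fixed before the data were examined: pseudocounts of 0.01 and 1, a mean RPKM of at least 5, no filter, 3 other scalings and leaving out zeros. Others were a minimum of 10 reads in each library, matching of random lists on length as well or on mRNA RPKM alone, leaving out ribosomal protein genes, and detection at 0.1 RPKM. Restricting the table to NM records and using GENCODE lengths were added after seeing the data.

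The recovery of reads, the counting intervals, the 2-fold calls and the list percentiles were tested on simulated reads for the same genes and depths. The ratios of 200 genes were shifted by 1.5 or 3 on the log2 scale in either direction. These genes had a mean of at least 2 RPKM, so shifts of the weakest expressed genes were not tested. The simulated reads held Poisson counting error only, without variation from PCR, library preparation or culture. Both library totals were recovered, and the fewest reads were at or below the true reads for 100.0% of 13415 genes. The counting interval held the true ratio for 96.2% of those genes. Of 50 genes per shift, 98.0% were called at least 2-fold above the median at a shift of 1.5 and 100.0% at a shift of 3. Of 12718 unchanged genes, 0.84% were called, which is a rate from counting error and not the rate of false calls in the data. All 20 simulated lists raised by 0.5 stood above their matched lists, where all unchanged genes shared the same true ratio. The real ratios differ between genes, with quartiles of -0.42 and 0.29, so this is not the power for real lists. Of 200 unchanged lists, drawn at random, 4.5% stood apart, which does not test lists of related genes. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Biopython 1.88, with matplotlib 3.10.9 for figures.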

Results

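Gene expression in Caco-2 cells was measured at 2 levels, polyadenylated RNA from total RNA and polyadenylated RNA recovered with translating ribosomes. The mRNA library held 9640364 reads and the RNC-mRNA library 11083302. The design asks how the translated mRNA population differs from the total mRNA population. With 1 library per level, each difference below describes this pair of libraries and has no replicate check. The labels do not state whether both RNA preparations came from the same culture, so each translation ratio can also hold a difference between cultures. Translation ratios are log2 values relative to the median of all expressed genes, and paired levels give the mRNA library first.

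The most abundant records of both libraries included mRNAs of a growth factor, glycolysis and the translation machinery, and also MTRNR2L2, MTRNR2L8 and MIR4461. IGF2, which encodes a fetal growth factor, had 5280 RPKM in the mRNA library and 4698 RPKM in the RNC-mRNA library. GAPDH, a glycolytic enzyme, had 5269 and 5435 RPKM. The ribosomal protein genes RPS2 (4087 and 4247 RPKM) and RPL41 (3736 and 3420 RPKM) and the elongation factor EEF1A1 (2600 and 2964 RPKM) were also among the 10 most abundant in both. TPT1, a translationally controlled tumour protein mRNA, had 2617 and 1977 RPKM and RPS27 had 2365 and 1883 RPKM, and both were in the first 10 of the mRNA library alone. The cytoskeletal actin ACTB and the ribosome scaffold GNB2L1 (RACK1) were in the first 10 of the RNC-mRNA library alone. ACTB had 1812 RPKM in the mRNA library and 2938 RPKM in the RNC-mRNA library, and GNB2L1 had 2301 and 2295 RPKM. MTRNR2L2 (5229 and 4752 RPKM), MTRNR2L8 (3088 and 3202 RPKM) and MIR4461 (4815 and 3064 RPKM) complete these lists. MIR4461 was taken as 74 nt long, so its RPKM rests on few reads for its level, at least 3435 and 2513. The MTRNR2L genes resemble mitochondrial ribosomal RNA and many ribosomal protein genes have processed pseudogenes, so the reads of both groups are uncertain.

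The 10 most abundant genes held 8.5% of the summed RPKM in the mRNA library and 8.0% in the RNC-mRNA library, and the 100 most abundant held 32.0% and 30.2%. At a level of at least 1 RPKM, 13910 genes were detected in the mRNA library and 12636 in the RNC-mRNA library. Of these, 12443 were shared, 1467 reached that level in the mRNA library alone and 193 in the RNC-mRNA library alone.

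The immediate early genes EGR1 and FOS had the highest translation ratios among genes with a mean RPKM of at least 10. EGR1, a zinc-finger transcription factor induced within minutes of stimulation, had 4.60 RPKM in the mRNA library and 78.4 RPKM in the RNC-mRNA library, a ratio 17.2-fold above the median gene (4.10 on the log2 scale, counting interval 3.88 to 4.39). FOS, an AP-1 subunit, had 6.68 and 27.8 RPKM (2.08, interval 1.83 to 2.37). The forkhead factor FOXQ1 (1.99), the secreted Wnt antagonist DKK1 (1.96, from 39.8 to 151 RPKM) and the non-coding HOXB-AS3 (1.94) followed. HOXB-AS3 is an antisense RNA, and its reads cannot be told from sense reads where strand is not recorded. The stress-induced cytokine GDF15 (1.82), the basic helix-loop-helix factor HAND1 (1.81), the small GTPase RASD1 (1.81), the actin-binding protein TAGLN (1.80) and LRRN4 (1.61) completed the 10 highest. For each of these 10 genes the lower counting limit lay above 1, the 2-fold line.

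The 10 lowest ratios belonged mostly to non-coding (NR) records, with ATHL1 and MIR205HG as protein-coding (NM) records. SNORA12, a small nucleolar RNA, had 24.0 RPKM in the mRNA library and was listed at 0 in the RNC-mRNA library. It was 13.0-fold lower with 3 reads taken as the floor, and the upper counting limit of its relative ratio was -3.29. RPPH1, the RNA subunit of ribonuclease P, had 41.4 and 0.529 RPKM (-6.00, interval -9.31 to -4.37, on at least 2 RNC-mRNA reads). MIR663A rested on as few as 1 RNC-mRNA read (-5.15, interval -10.64 to -2.72). SCARNA9, a Cajal body RNA, had 106 and 4.35 RPKM (-4.54), and LINC00685 (-4.35), the ribosomal RNA precursor RNA45S5 (-3.82) and the microRNA host MIR205HG (-3.64) lay close behind. ATHL1, also called PGGHG, which encodes a glucosidase, had 67.9 and 5.38 RPKM (-3.59, interval -3.84 to -3.41). The pseudogene PDXDC2P (-3.43) came next. Both libraries were made from poly(A) RNA, and how much of RNAs such as SNORA12, RPPH1, SCARNA9 and RNA45S5 carries a poly(A) tail was not measured. Their low ratios can therefore hold a difference in poly(A) selection between the libraries.

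Levels in the 2 libraries were closely correlated. Across the 13402 expressed genes, Spearman's rho between the levels was 0.941 and Pearson's r of the log2 levels was 0.928, both across genes, which are not independent replicates. The median log2 translation ratio was -0.04, and 86.9% of genes lay within 2-fold of it. The spread was uneven, with 184 genes at least 2-fold above the median and 1576 at least 2-fold below. The counting interval excluded the median for 157 of the 184 and for 1447 of the 1576. It lay wholly beyond the 2-fold line for 59 of the 184 and 790 of the 1576. These counts depend on the filter on low values and on the pseudocount. With a pseudocount of 1 RPKM they were 102 and 1046. With a mean RPKM of at least 5 they were 62 and 544, and with no filter 599 and 3040.

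**Figure D1:**
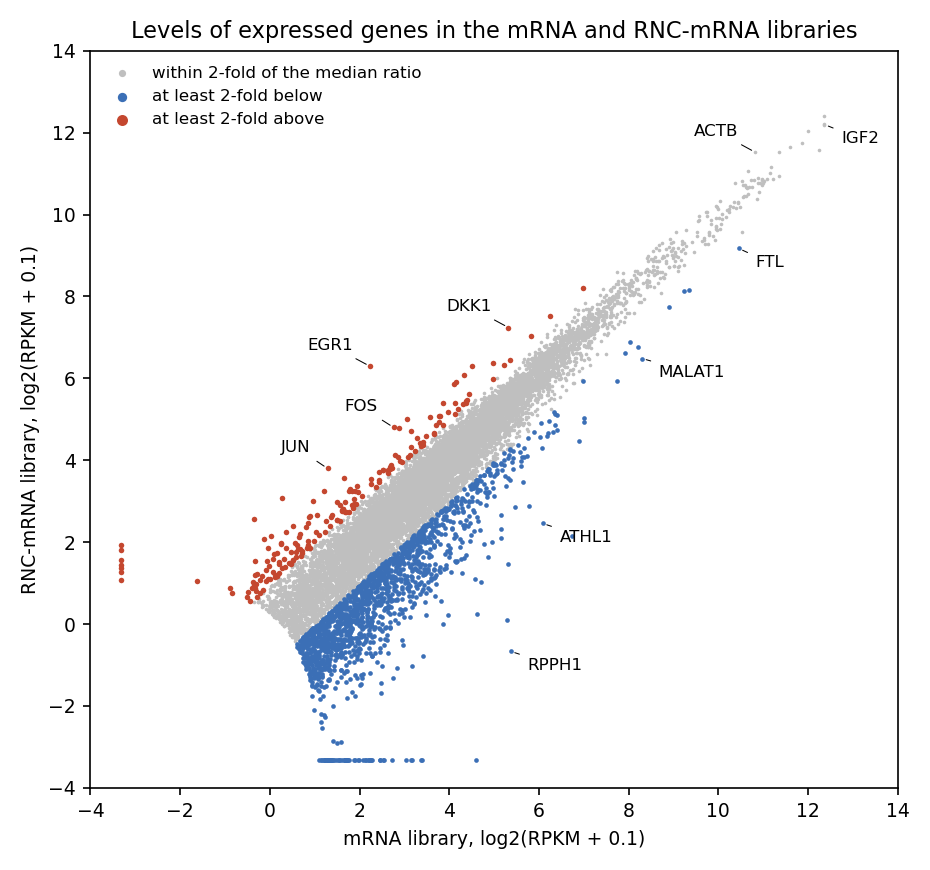
Level of each expressed gene in the mRNA library (x axis) and the RNC-mRNA library (y axis), both as log2(RPKM + 0.1), 1 point per gene and 1 library per axis. Red points are the 184 genes at least 2-fold above the median ratio and blue points the 1576 at least 2-fold below, which lie mostly at low levels; points in straight lines at the edges are genes listed at 0 in 1 library.

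NM and NR records differed in where they lay. This is not a clean contrast of coding with non-coding genes, since protein-coding genes such as KRT8, MRPL10, PDHB, CARS and SARS are among the NR records. The 11940 expressed NM records had a median relative ratio of 0.03 (95% interval 0.02 to 0.04), and 8.9% of them were at least 2-fold below the median. The 1462 expressed NR records had a median of -0.47 (interval -0.53 to -0.41), with 35.3% at least 2-fold below. Random sets of other genes matched on expression gave medians between -0.15 and -0.07. Among the 30 expressed small nucleolar RNA hosts and nuclear long non-coding RNAs, 25 lay below the median and 10 were at least 2-fold below (median -0.50, interval -1.12 to -0.29, percentile 0.00). MALAT1, a nuclear speckle RNA, had 316 RPKM in the mRNA library and 89.4 RPKM in the RNC-mRNA library (-1.78). Presence in the RNC-mRNA library is therefore not by itself evidence of translation. The imprinted H19 had 241 and 97.9 RPKM (-1.26). The telomerase RNA TERC (-3.02, interval -5.59 to -1.51), the imprinted antisense KCNQ1OT1 (-2.62) and the microRNA host MIR17HG (-2.41) were lower still. DANCR was the highest member at 0.32, with 80.8 and 98.6 RPKM.

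Of 33 gene lists with at least 5 expressed members, 3 stood above and 9 below their expression-matched random lists, where chance alone would give about 1.7 in all. Immediate early genes stood highest, with 17 of 22 expressed members above the median and 8 at least 2-fold above (median 0.62, interval 0.07 to 1.77, percentile 100). Besides EGR1 and FOS, the AP-1 subunit JUN had 2.34 and 13.8 RPKM (2.55). The matricellular CYR61 had 2.22 and 9.48 RPKM (2.09), and the MAP kinase phosphatase DUSP1 had 3.02 and 11.8 RPKM (1.96). JUND, the most abundant member, was near the median (0.20), and the stress-induced ATF3 was below it (-0.51).

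Wnt target genes lay above the median in 16 of 20 cases, 3 of them by at least 2-fold (median 0.44, interval 0.01 to 0.67, percentile 99.99). DKK1 led, followed by the transcription factor SP5 (1.06), the hyaluronan receptor CD44 (1.01), the intestinal stem cell receptor LGR5 (0.88) and SOX9 (0.76). NOTUM, a secreted Wnt deacylase, was the most abundant after DKK1 and had a ratio near the median (-0.08), and the Wnt inhibitor APCDD1 was lowest at -0.64.

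Replication-dependent histones lay above the median in 24 of 25 cases, 7 of them by at least 2-fold (median 0.38, interval 0.19 to 0.93, percentile 100). HIST1H4E had 1.10 and 8.38 RPKM (2.86, interval 1.48 to 4.92), and the linker histone HIST1H1E had 1.85 and 7.93 RPKM (2.08). HIST4H4 (1.78, interval 0.61 to 3.28) and HIST1H3H (1.75, interval 0.38 to 3.61) followed. HIST1H3B was listed at 0 in the mRNA library and rested on at least 3 RNC-mRNA reads, so no fold is given. The 2 most abundant members, HIST1H2BK (0.14) and HIST1H4C (0.02), were near the median, and HIST1H2BJ was lowest (-0.29). Most of these mRNAs lack a poly(A) tail, so poly(A) libraries hold only part of them. With genes of a mean RPKM of at least 5 alone, the list's median was 0.13 at percentile 85.63 and it no longer stood apart.

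Cytosolic ribosomal protein mRNAs lay slightly below the median as a group, whereas random lists from the same expression bins lay above it. Of 79 members, 61 were below the median, and none differed from it by 2-fold (median -0.11, interval -0.16 to -0.07, percentile 0.00). The match on expression is coarse here: the list's median level was 994.1 and 844.7 RPKM, and that of the highest expression decile was 101.6 RPKM. The percentile therefore cannot separate ribosomal protein mRNAs from other very abundant mRNAs. RPL34 (-0.66), RPL23 (-0.52), RPL22 (-0.50) and RPL21 (-0.46) were among the lowest, and RPS26 was highest (0.46). The other mRNAs with a 5' terminal oligopyrimidine tract did not stand apart (20 expressed, median 0.10, percentile 27.56), with TPT1 lowest (-0.37), the filament protein VIM highest (0.88) and EEF1A1 at 0.23. Aminoacyl-tRNA synthetases, which charge transfer RNAs, had a median of -0.02 in 20 members at percentile 2.27, with CARS (-0.48), SARS (-0.27), LARS (-0.27), RARS (-0.26) and DARS (-0.25) lowest. VARS was highest (0.41), and the abundant KARS and QARS had ratios of 0.37 and -0.02. This call was lost when random lists were matched on mRNA RPKM alone (percentile 8.12) and with NM records alone, an alternative chosen after seeing the data (percentile 3.14). The NM records leave out CARS and SARS, which are paired with NR records. With no filter the list's median was 0.08 at percentile 2.32. Translation initiation factors had a median of 0.27 in 33 members and did not stand apart (percentile 96.66). EIF4G2 was highest (0.89) and EIF5B lowest (-0.94), with EIF5A at 0.55 and EIF4A1 at 0.39.

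Lists of enterocyte genes, hepatic-type secreted proteins, epithelial keratins and adhesion genes, and goblet, Paneth, enteroendocrine and tuft markers stood below their matched lists. The interval of each of these lists spanned the median of all expressed genes. Enterocyte brush border and differentiation genes had a median of -0.21 in 27 expressed members (interval -0.56 to 0.18, percentile 0.20). The alkaline phosphatases ALPPL2 (85.1 and 26.6 RPKM, -1.63) and ALPP (-0.87), the guanylin receptor GUCY2C (-1.18), the microvillar cadherin CDHR2 (-1.76) and the brush border myosin MYO1A (-0.85) were lowest. The fatty acid-binding protein FABP1 had 137 and 90.7 RPKM (-0.56), the membrane linker EZR was near the median (-0.06), and the transcription factor GATA6 was highest (1.03). ALPP and ALPPL2 are close paralogs, so their shares of reads are uncertain. Apolipoproteins and other hepatic-type secreted proteins had 17 of 24 members below the median (median -0.22, interval -0.48 to 0.07, percentile 0.01). APOA1, the main protein of high-density lipoprotein, had 1874 and 1322 RPKM (-0.46), and APOE had 825 and 666 RPKM (-0.27). AFP (127 and 61.1 RPKM, -1.02), APOA4 (-1.0, counting interval -1.95 to -0.17), complement C3 (-0.99), ALB (-0.66) and APOM (-0.61) were lowest. The RNA-binding APOB editing cofactor A1CF was highest (0.44).

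Epithelial keratins and adhesion genes had a median of -0.10 in 32 members (interval -0.34 to 0.13, percentile 0.23), and of 0.01 at percentile 0.26 with no filter on low values. The carcinoembryonic antigens CEACAM5 (9.85 and 1.86 RPKM, -2.31) and CEACAM6 (-0.94), the desmosomal DSP (84.4 and 34.3 RPKM, -1.26), the tight junction protein CGN (-1.13) and the galectin LGALS4 (-1.13) were lowest. The counting interval of LGALS4 was -2.41 to -0.13. The abundant keratins KRT8 (0.22) and KRT18 (-0.04) were near the median, and the desmosomal PKP2 was highest (1.12). Markers of goblet, Paneth, enteroendocrine and tuft cells had 8 of 22 members expressed, 7 of them below the median (median -0.70, interval -1.80 to 0.12, percentile 0.07). The tuft cell factor POU2F3 (-1.80), the defensin DEFA6 (-1.74), the trefoil peptides TFF2 (-1.05) and TFF1 (-0.85) and the lysozyme LYZ (-0.54) were lowest. The counting intervals were -3.64 to -0.33 for DEFA6, -1.58 to -0.55 for TFF2 and -1.36 to -0.36 for TFF1. The abundant TFF3 had a ratio of -0.30, and the disulfide isomerase AGR2 was highest (0.12). With no filter on low values this list no longer stood apart (percentile 29.45).

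Fibroblast and matrix markers had a median of -0.59 in 16 expressed members (interval -1.10 to 0.48, percentile 0.23) and went both ways. FN1, a matrix glycoprotein, had 298 and 108 RPKM (-1.42). POSTN (-1.80, interval -4.52 to -0.12), COL6A2 (-1.34), COL6A3 (-1.10) and COL1A2 (-1.03) were also at least 2-fold below, whereas TAGLN was highest and the abundant SPARC was at 0.26. With no filter this list no longer stood apart (percentile 13.98). The 398 expressed zinc-finger genes named ZNF, most of which encode transcription regulators, had a median of -0.25 (interval -0.33 to -0.17, percentile 0.55), with 68 at least 2-fold below and 0 at least 2-fold above. ZNF671 had 2.34 RPKM in the mRNA library and was listed at 0 in the RNC-mRNA library. It was 21.1-fold lower with 3 reads taken as the floor, and the upper counting limit of its relative ratio was -4.01. ZNF154 rested on as few as 1 RNC-mRNA read (-4.37, interval -11.66 to -3.81), and ZNF483 (-2.81), ZNF471 (-2.52) and ZNF835 (-2.24) followed. The abundant ZNF259 (0.49) and ZNF207 (0.31) and the highest member ZNF597 (0.94) were above the median. The ZNF call was lost with a mean RPKM of at least 5 (percentile 3.87) and with no filter (percentile 7.06).

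**Figure D2:**
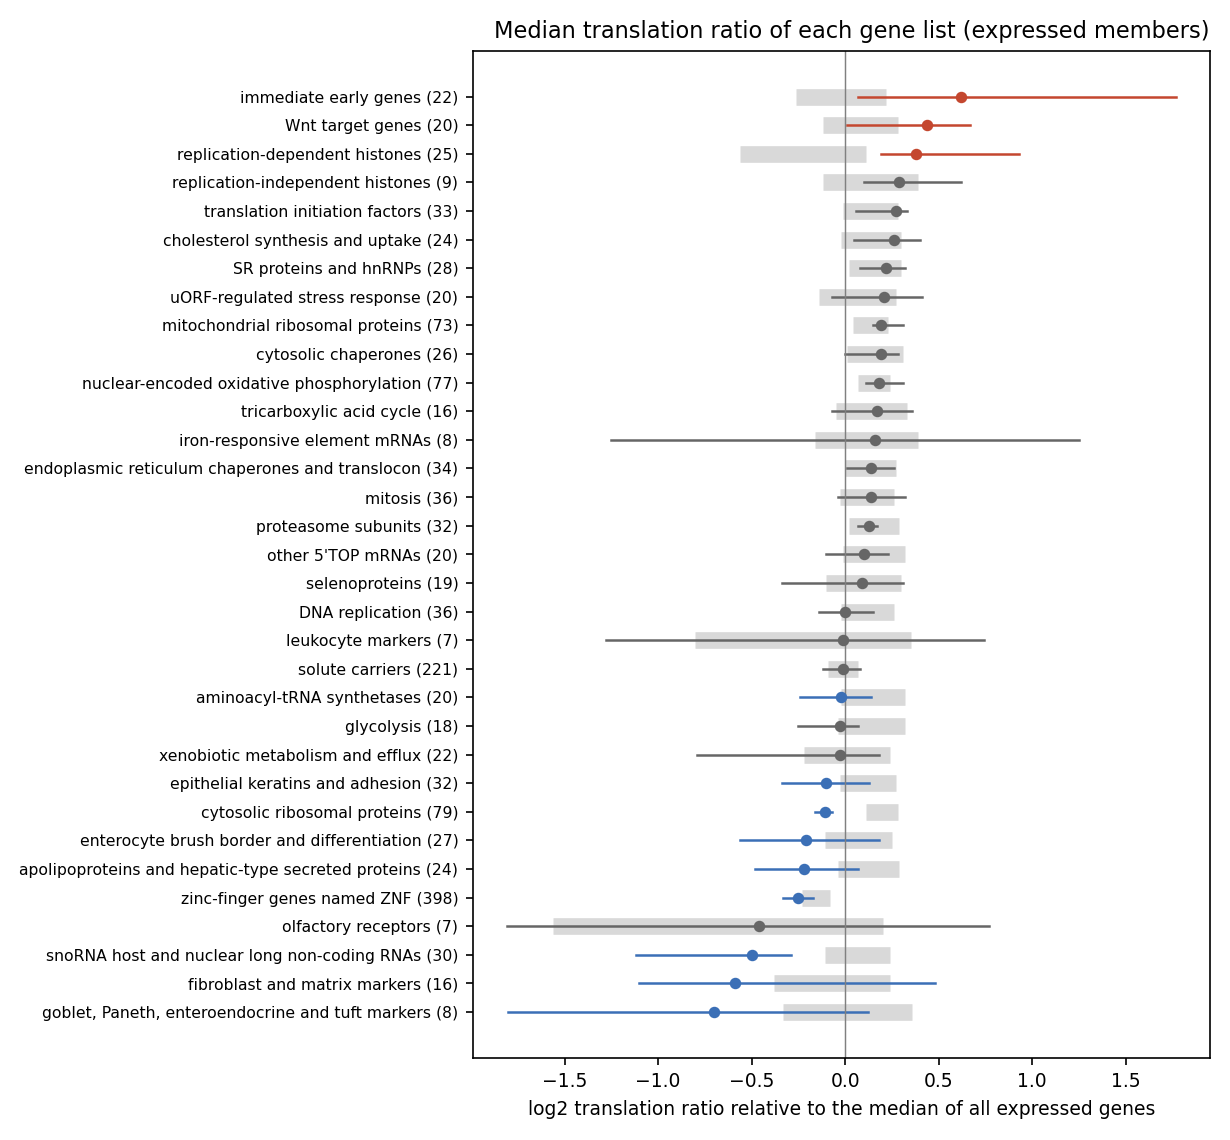
Median log2 translation ratio of the expressed members of each list relative to all expressed genes (points), with the 95% order-statistic interval of the median over members (lines) and the central 95% of 10000 expression-matched random lists (grey bars); the number of expressed members is in parentheses. Red lists (3) stood above and blue lists (9) below their random lists, and cytosolic ribosomal proteins at -0.11 lie outside a grey bar that is wholly above 0.

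Housekeeping machinery lay close to or slightly above the median and did not stand apart. Mitochondrial ribosomal proteins had a median of 0.19 in 73 members (percentile 87.49), from MRPS6 (-0.73) to MRPL1 (0.67), with the abundant MRPL51 at 0.24 and MRPL10 at 0.43. Nuclear-encoded oxidative phosphorylation genes had a median of 0.18 in 77 members (percentile 68.73), from NDUFB1 (-0.54) to ATP5G3 (0.74), with COX6B1 at 0.38 and ATP5E at 0.13. Proteasome subunits had a median of 0.13 in 32 members (percentile 31.46), from PSMD13 (-0.22) to PSMB2 (0.50), with PSMB3 at 0.26 and PSMA7 at 0.32. Glycolysis genes had a median of -0.03 in 18 members (percentile 3.49), from the neuronal enolase ENO2 (-1.70) to PGAM1 (0.33), with GAPDH at 0.08 and TPI1 at 0.07. The tricarboxylic acid cycle had a median of 0.17 in 16 members (percentile 60.39), from PDHB (-0.18) to DLAT (0.71), with MDH2 at 0.52 and SUCLG1 at 0.21. Cholesterol synthesis and uptake had a median of 0.26 in 24 members (percentile 91.93), with FDPS lowest (-0.27) and DHCR7 at 0.51.

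Stress, proliferation and RNA-processing lists also did not stand apart. The stress-response list of mRNAs with regulatory upstream reading frames had a median of 0.21 in 20 members (percentile 91.50), with ATF4 at 0.01, ODC1 at 0.75, AZIN1 highest (0.76) and the cystine transporter SLC7A11 lowest (-1.36). Endoplasmic reticulum chaperones had a median of 0.14 in 34 members (percentile 47.94), from HSP90B1 (-0.49) to SPCS1 (0.62), with CALR at -0.01 and P4HB at -0.02. Cytosolic chaperones had a median of 0.19 in 26 members (percentile 66.02), from HSPA1A (-0.51) to HSPH1 (0.50), with HSPA8 at 0.26 and HSP90AB1 at 0.10. DNA replication genes had a median of 0.00 in 36 members (percentile 4.49), from POLE (-0.72) to RRM2 (0.65), with MCM7 at -0.24 and PCNA at 0.18. Mitosis genes had a median of 0.14 in 36 members (percentile 60.11), from CENPE (-1.17) to CCNA2 (0.81), with UBE2C at 0.50 and PTTG1 at 0.00. Replication-independent histones were above the median in 9 of 9 cases (median 0.29, percentile 86.00), led by H2AFX (0.69), with H3F3A at 0.29 and H1FX lowest at 0.07. SR proteins and hnRNPs had a median of 0.22 in 28 members (percentile 79.44), from SRSF11 (-1.01) to HNRNPF (0.62), with HNRNPL at 0.38 and HNRNPK at 0.32.

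Among lists defined by regulation or transport, the iron-responsive element mRNAs went both ways. The ferritin subunits FTL (1405 and 576 RPKM, -1.25) and FTH1 (1472 and 757 RPKM, -0.92), which store iron, were lowest and most abundant, and the hypoxia factor EPAS1 was highest (1.25). The list's median was 0.16 in 8 members (percentile 56.97). Selenoproteins had a median of 0.09 in 19 members (percentile 39.93), from SELO (-0.63) to SELT (0.83), with GPX4 at 0.36 and SEPW1 at -0.48. Xenobiotic metabolism and efflux genes had a median of -0.03 in 22 members (percentile 30.06), from the dioxin-inducible CYP1A1 (5.77 and 1.18 RPKM, -2.16) to the efflux pump ABCB1 (0.81), with GSTP1 at 0.32 and POR at 0.18. Solute carriers had a median of -0.01 in 221 members (percentile 49.97), from the nucleoside carrier SLC28A2 (-2.47) to the zinc exporter SLC30A1 (1.15), with SLC2A3 at -0.01 and SLC25A6 at 0.20. Of the metallothioneins, 3 were expressed, MT2A (-0.05), MT1F (-1.03) and MT1A (0.30).

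Some markers of cell types other than epithelium passed the expression filter. Of 18 leukocyte markers, 7 were expressed (median -0.01, percentile 63.22), with LCP1 at 23.7 RPKM in both libraries, CD68 at 13.0 and 12.5 RPKM, CSF1R at 0.74 and CD3G at -1.28 in ratio. Of 14 endothelial and erythroid markers, 3 were expressed, among them PECAM1 (4.12 and 1.58 RPKM) and HBA2 (0.686 and 5.82 RPKM). Of 14 neuronal markers, 3 were expressed, among them GAD1 (2.90 and 1.17 RPKM) and MBP (2.29 and 3.01 RPKM). Of 397 olfactory receptor genes, 7 were expressed (median -0.46, percentile 49.01), with OR7E12P at 6.95 and 2.39 RPKM and OR7E14P at 4.12 and 3.04 RPKM. OR10A2 was highest in ratio (0.77) and OR7D2 lowest (-1.81).

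Weakly expressed genes had lower translation ratios than abundant ones. Spearman's rho between mean log2 RPKM and the log2 ratio was 0.34 across genes, and 0.20 with genes of a mean RPKM of at least 5 alone. The lowest expression decile had a median relative ratio of -0.79 (interval -0.88 to -0.71), with 45.1% of genes at least 2-fold below the median and 3.1% at least 2-fold above. The highest decile had a median of 0.17 (interval 0.15 to 0.20), with 0.9% and 0.4%. NR records made up 28.6% of the lowest decile and 5.8% of the highest. With deciles of the arithmetic mean RPKM, the quantity used to filter genes, the lowest decile had a median of -0.57.

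Transcript length had little relation to the ratio. Spearman's rho was 0.04 over 13177 genes, and between 0.05 and 0.16 within 5 bins of expression. The shortest decile had a median of -0.06 (interval -0.10 to -0.02) and the longest a median of -0.04. With NM records alone, an alternative chosen after seeing the data, rho was -0.01.

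**Figure D3:**
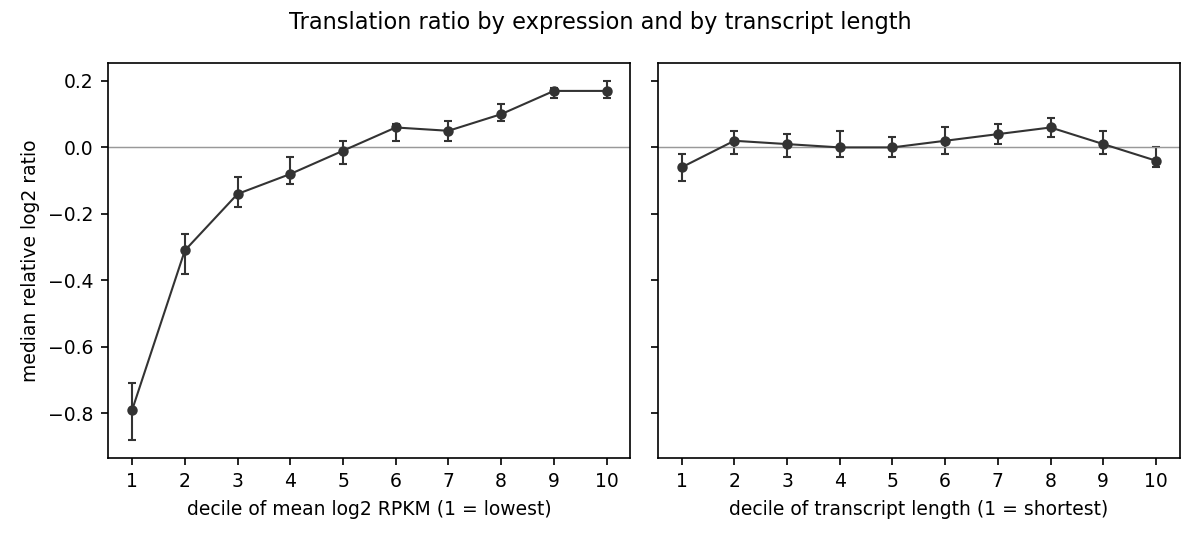
Median log2 translation ratio relative to all expressed genes (y axis, no unit) by decile of mean log2 RPKM (left) and of transcript length (right), with 95% order-statistic intervals of the median over genes as bars. The median is higher with each step of expression from -0.79 in decile 1 to 0.10 in decile 8, apart from decile 7, and lies between -0.06 and 0.06 across length.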

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

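Restricting genes to NM records and using GENCODE transcript lengths were chosen after seeing the data; all other alternatives were planned. Summing rows of 1 symbol was not run, because no symbol was repeated. No paired analysis was possible because each group has 1 library. Immediate early genes, Wnt targets, ribosomal proteins, enterocyte genes, apolipoproteins and long non-coding RNAs kept their direction and stood apart under every alternative run. Over those alternatives the immediate early median ranged from 0.39 to 0.64, the Wnt median from 0.35 to 0.54 and the ribosomal protein median from -0.19 to -0.01. Of the single-gene ratios of named genes, 1900 recomputed values kept their side of the 2-fold line, 38 crossed it and none of the 2-fold ones changed sign.

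A pseudocount of 1 gave 102 genes at least 2-fold above and 1046 below, all of them among the 184 and 1576. With a mean RPKM of at least 5, which tests fewer genes, the counts were 62 and 544, of which 62 and 474 were among the 184 and 1576. The median log2 ratio was then 0.04, rho between the levels 0.912, rho with length 0.02 and rho with expression 0.20. Replication-dependent histones (0.13) and ZNF genes (-0.16) no longer stood apart, and the upstream reading frame list (0.22, percentile 97.82) did. With no filter, which adds genes near 0, the counts were 599 and 3040, which held all of the 184 but 1381 of the 1576. The median was then -0.14, rho between the levels 0.959 and rho with length 0.08. Goblet and related markers (-0.21), fibroblast markers (-0.09) and ZNF genes (-0.18) then no longer stood apart. The medians of aminoacyl-tRNA synthetases (0.08) and epithelial adhesion genes (0.01) changed sign, although both stayed below their matched lists at percentiles 2.32 and 0.26.

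The median log2 ratio was -0.07 with upper quartile scaling and 0.01 with a trimmed mean of log ratios; ratios relative to the median are centred again under each scaling. With at least 10 reads in each library the median was -0.02, rho between the levels 0.946, rho with length -0.00 and rho with expression 0.31. With NM records alone these were -0.01, 0.951, -0.01 and 0.30, and aminoacyl-tRNA synthetases (-0.05, percentile 3.14) no longer stood apart. Matching on length as well placed glycolysis (-0.03) at percentile 1.71. Matching on mRNA RPKM alone gave 5 lists above, adding initiation factors (0.27, percentile 99.23) and mitochondrial ribosomal proteins (0.19, percentile 97.56), and ended the call of aminoacyl-tRNA synthetases (-0.02). Where no reason is given, the cause was not tested. Depth limits weak genes most, since 510 expressed genes rest on possibly fewer than 10 reads in at least 1 library.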

Other observations

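Among protein-coding records with a mean RPKM of at least 10, the lowest ratios belonged to an unlike set of genes, named here after their values were seen. LUC7L3, a splicing-related protein, was the most abundant at 118.5 RPKM in the mRNA library and 22.1 RPKM in the RNC-mRNA library (-2.38, interval -2.49 to -2.28). The fast skeletal troponin TNNT3 had 35.4 and 4.20 RPKM (-3.01), TMEM212 had 54.8 and 7.24 RPKM (-2.86), and the chemokine CCL5 had 19.9 and 2.94 RPKM (-2.68). KIAA1984 (-2.66), the anoctamin ANO9 (-2.57), MST1 (-2.53) and ODF2L (-2.45) followed. MIR205HG and ATHL1, given in the report, had lower ratios than all of these.

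The parts of a transcript were related to the ratio in different directions, in a comparison chosen after seeing the data. Across 11587 NM records, rho with the log2 ratio was -0.11 for coding length, 0.12 for 3' UTR length and 0.08 for 5' UTR length. These are correlations across genes of 1 pair of libraries, and they were not repeated within bins of expression. For the whole transcript length of NM records, rho was -0.01 across all of them and between 0.05 and 0.10 within 5 bins of expression. A part of each correlation may thus come from expression.

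In the 3 patterns below, the tests of counting error, of the source of the cells and of solute carriers were chosen only after the result was seen. The design gives no group beyond the 2 RNA fractions, so no biological explanation was tested.

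Weakly expressed genes sat low in the RNC-mRNA library, at -0.79 in the lowest decile. Background of the size seen at silent genes does not account for this. The 390 olfactory receptor genes with a mean RPKM below 1 averaged 0.0233 RPKM in the mRNA library and 0.0117 in the RNC-mRNA library. Their sums, 9.097 and 4.569 RPKM, fell just short of the 2-fold difference set beforehand. Subtracting these means left the decile, with a median level of 1.368 RPKM, at -0.79. Receptors above that cut were left out, and background at transcribed genes was not measured, so a larger background there stays open. NR records are not the whole cause, since the lowest decile of NM records alone was at -0.55. The filter on the arithmetic mean is not either, since deciles of that mean gave -0.57 (interval -0.65 to -0.50), although both values are nearer 0 and each may account for part. Nuclear RNA that ribosomes do not reach is a candidate explanation that stays open.

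Immediate early mRNAs sat high in the RNC-mRNA library. Counting error alone is argued against, because 13 of all 22 expressed members had a lower counting limit above the median. Counting error alone would give about 0.55, and 2 members had an upper limit below the median. The share of all expressed genes with a lower limit above the median is not given, so this count does not set the list apart. If EGR1 reached even the lower counting limit of its ratio (3.88) by ribosome binding alone, at most 6.8% of the median mRNA could have been bound, a share that no value here measures. These mRNAs are induced within minutes, so the cells used for the RNC-mRNA library may have held more of them. This cannot be told apart from translation, because any difference between the cells used is confounded with the RNA fraction. More libraries made in the same way would not separate the explanations. Total RNA from the very lysate used for ribosome recovery would separate the explanations.

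Hepatic-type secreted protein mRNAs sat low in the RNC-mRNA library, at -0.22 (interval -0.48 to 0.07). A loss of all mRNAs read at the endoplasmic reticulum stays open. The 181 solute carriers outside the mitochondrial SLC25 family had a median of -0.07 (interval -0.18 to 0.04) at percentile 11.18. The 34 endoplasmic reticulum chaperone and translocon genes had a median of 0.14 (interval 0.01 to 0.26) at percentile 47.94. Neither set stood apart, which a loss of the whole class would not give, but both intervals overlap that of the hepatic-type list. Genes with a hydrophobic stretch near the N terminus, 1050 in number, lay -0.08 (interval -0.12 to -0.03) from expression-matched genes without one, at percentile 0.00. This difference fell between the bounds set beforehand (-0.1 for a loss and -0.05 against it), so a small loss of mRNAs with signal sequences may contribute and stays open.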
